A study of Caenorhabditis elegans with 9 samples.

How the data were processed

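Gene expression was measured in C. elegans young adults on 9 arrays, 3 in each of 3 groups that the labels call empty vector, sams-1 RNAi and sbp-1 RNAi. Per the labels, the growth medium held ampicillin, tetracycline and 6 mM IPTG, which switches on the RNAi construct, and animals were harvested once 80% of them were young adults. Biotin-labelled cDNA was made from 500 ng of total RNA with an Affymetrix whole-transcript kit. The deposited table holds 1 RMA intensity per feature and array, where RMA stands for background correction, quantile normalization and probe summary, and the authors gave no version or software for it. RMA usually ends on the log2 scale, but the deposited intensity values ran from 2.045 to 15920 with array medians of 21.5 to 23.7, so they were read as linear and log2 was taken before any fit. The quartiles of the arrays were close but not equal, and no further scaling was applied.

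All 29317 features were tested, since no filter was planned and the table marks no control features. A single gene name was available for 25600 features (87.3%), 592 features carried several names and 3125 carried none. The names covered 25528 genes, of which 61 had more than 1 feature, and 769 features had the same 9 values as another feature. A feature with several names or none was counted in the totals but not called by a gene name. No genome build was given for the array, so no positions are stated.

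Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with a mean per group was fitted to all 9 arrays with lmFit and eBayes, so that every comparison drew on the spread within all 3 groups. Each RNAi group was compared with empty vector and with the other RNAi group, and limma's F test asked for any difference among the 3 groups. P-values were two-sided and adjusted with the Benjamini-Hochberg method over all features within a comparison, and a feature was called at an adjusted p under 0.05. They measure only the spread between these 9 arrays. The array number limits the precision: the median standard error of a log2 fold change was 0.168.

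The groups, the tests, 24 gene lists and 15 gene families picked by name were fixed before the data were examined, as was the rule for naming genes. The rule names both targeted genes, 13 fixed genes of known interest to the study, the 10 largest rises and the 10 largest falls among called features with 1 gene name and no overlap between the arrays of the groups compared, and up to 4 members with the smallest adjusted p of each list that was called or had at least 3 called members. Lists were tested with camera at a preset inter-gene correlation of 0.01, with 1 feature per gene (the brightest), and adjusted over the 39 lists and families within a comparison. Each test was repeated with a correlation estimated from the residuals. It was also repeated with fry, which asks whether the genes of a list move one way on balance and compares them with no other genes. A list was counted as called on the preset correlation.

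Since both RNAi groups were compared with the same 3 empty vector arrays, shared calls were set beside 100 simulations of unchanged groups (seed 11). In each, all 3 groups, empty vector included, were redrawn as random mixes of their own arrays' departures from the group mean. Both simulated RNAi groups were then compared with the same simulated empty vector group. Another 100 simulations used independent noise of the same SD for each feature. Features of interest were also compared between the RNAi groups directly. Replicate numbers in the titles were checked for pairing through the correlation, across features, of each array's departure from its group mean. Arrays of the same number correlated more than arrays of different numbers for sbp-1 RNAi and empty vector (0.119, 0.229 and 0.315 for numbers 1 to 3, against at most 0.0962). They did not for sams-1 RNAi and empty vector (0.127, -0.0480 and 0.0286) or for both RNAi groups (0.0595, -0.000746 and 0.0176). The labels state no block, and with 3 arrays per group such a match of numbers can arise by chance. The fit had been fixed without a replicate term and was kept so despite the correlations for sbp-1 RNAi and empty vector. Blocked values are given beside the sbp-1 RNAi comparison.

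Where 1 or both of 5 tissue means in a gap were picked, the gap was held to the 5% bound of the studentized range, 2.73 standard errors. These standard errors are over genes and leave out the spread between arrays.

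The fit was tested on simulated data built from these arrays. Among 100 features given a log2 change of 1, the sams-1 RNAi comparison recovered 58 and the sbp-1 RNAi comparison 54, and both recovered 94 of 100 at a change of 2. Of the unchanged features, 8 and 7 were called, and a shifted list of 25 genes was called with 0 other lists. The noise was drawn independently for each feature, so the genes of a list did not correlate. The list result therefore says nothing on lists whose genes correlate, such as germline markers (estimated correlation 0.648). Alternatives were a replicate block, a fit of only the groups compared, quantile normalization, median centring, cyclic loess, leaving out features under the 30th percentile of mean intensity (log2 3.43), a trended robust eBayes fit, array weights, a 2-fold minimum, the mean of a gene's features, and leaving out each array in turn. A fit of only the features with 1 gene name was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.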

Results

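The series set out to compare gene expression after 2 RNAi treatments in adult C. elegans. The gene sams-1 encodes an S-adenosylmethionine synthase, which makes the methyl donor used to build phosphatidylcholine, and sbp-1 encodes the worm's SREBP, a transcription factor for lipid synthesis genes. Each group had 3 arrays, and every array gave an RMA intensity for 29317 features. Linear array medians for replicates 1 to 3 were 22.8, 23.7 and 22.6 in empty vector, 21.8, 21.5 and 22.9 in sams-1 RNAi, and 22.01, 22.6 and 22.6 in sbp-1 RNAi. Empty vector array 3 stood apart, with a residual SD of 0.330 (log2) against 0.187 to 0.254 for the other 8 arrays.

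The targeted genes were read first. The gene sams-1 measured 10.99 ± 0.19 in empty vector, 10.49 ± 0.70 in arrays labelled sams-1 RNAi and 9.89 ± 0.62 in arrays labelled sbp-1 RNAi (log2 intensity, mean ± SD, n = 3 each). Against empty vector it differed by -0.50 in the arrays labelled for it (SE 0.37, adjusted p 0.431) and by -1.097 in the arrays labelled sbp-1 RNAi (SE 0.37, adjusted p 0.220). The gene sbp-1 measured 7.64 ± 0.11 in empty vector, 8.05 ± 0.17 in sams-1 RNAi and 7.55 ± 0.22 in sbp-1 RNAi, a difference of -0.08 in the arrays labelled for it (SE 0.15, adjusted p 0.863) and of 0.41 in the others (adjusted p 0.128). The RNAi groups differed by 0.60 in sams-1 (adjusted p 0.584) and by 0.49 in sbp-1 (adjusted p 0.168). Each targeted gene was read by 1 feature, and neither was called in any comparison or under any alternative. The array therefore does not bear out the labels through the targeted genes, so every direction below belongs to the arrays as labelled.

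**Figure D1:**
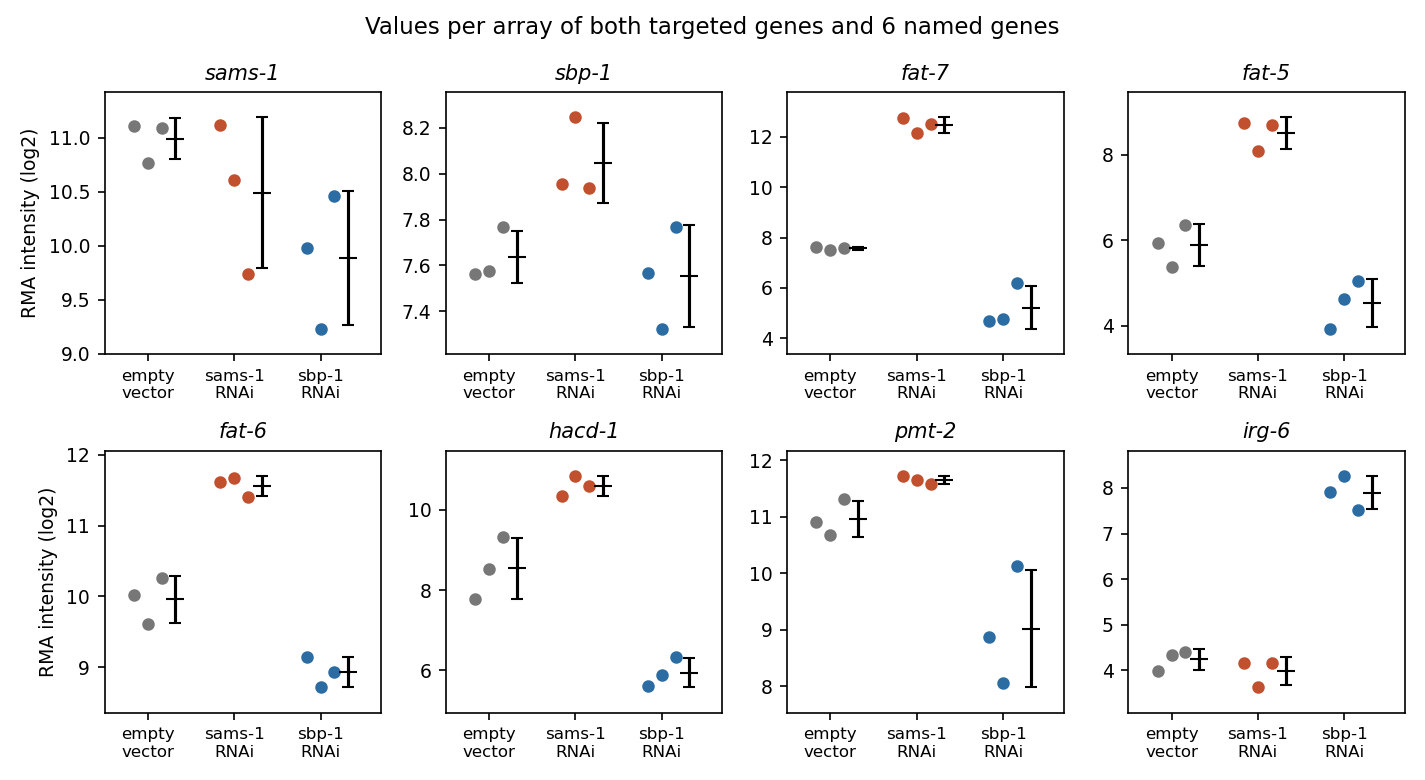
Values per array (log2 RMA intensity) of both targeted genes and 6 named genes in the 3 groups, with points for arrays, bars for the mean and whiskers for 1 SD of 3 arrays. The gene sams-1 spans 9.74 to 11.12 in the arrays labelled for it, while fat-7 stands at 12.47 on average in sams-1 RNAi, 7.57 in empty vector and 5.22 in sbp-1 RNAi.

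In arrays labelled sams-1 RNAi, all 3 delta-9 desaturase genes, which make monounsaturated fatty acids, were higher than in empty vector. The gene fat-7 rose by 4.89 (log2, SE 0.35, adjusted p 9.07e-05), from 7.57 ± 0.06 to 12.47 ± 0.31 (SD, n = 3), fat-5 by 2.61 (SE 0.33, adjusted p 0.00171) and fat-6 by 1.59 (SE 0.18, adjusted p 0.00113). The triglyceride-making acyltransferase dgat-2 rose by 2.31 (SE 0.16, adjusted p 8.12e-05) and the acetyl-CoA carboxylase pod-2 by 0.81 (adjusted p 0.00404). The fatty acid synthase fasn-1 differed by 0.19 (SE 0.15, adjusted p 0.473). Among phospholipid genes, the kinase ckb-2 rose by 1.92, cept-1 by 1.55, the methyltransferase pmt-1 by 1.25 (SE 0.21, adjusted p 0.00729), the phosphatase lpin-1 by 1.02 and the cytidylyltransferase pcyt-1 by 0.85 (adjusted p 0.0176). The other methyltransferase, pmt-2, differed by 0.69 (SE 0.42, adjusted p 0.334). The methionine synthase metr-1 rose by 1.45 (SE 0.14, adjusted p 4.92e-04), its reductase mtrr-1 by 0.80 and mthf-1 by 0.89. In contrast, cth-1, which makes cysteine from cystathionine, fell by 1.5 (SE 0.18, adjusted p 0.00135) and cbs-1 differed by -0.35 (adjusted p 0.365). The propionate gene acdh-1 differed by 0.21 (SE 1.00, adjusted p 0.914).

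Of 17 genes on the p38 immune pathway list 11 were called higher in the arrays labelled sams-1 RNAi (list adjusted p 3.71e-09, and 0.129 with an estimated correlation). The phosphatase gene vhp-1 rose by 1.80 (SE 0.17, adjusted p 4.45e-04), nipi-3 by 1.62, cebp-1 by 1.54 and the kinase pmk-3 by 1.06. This list mixes kinases with genes that regulate them, so higher members do not show that the pathway was more active. Effector genes went both ways: irg-1 rose by 1.93 (SE 0.30, adjusted p 0.00480), hpo-6 by 2.20 and the lectin clec-83 by 1.16, and the saposin-like spp-1 fell by 2.20 (SE 0.15, adjusted p 7.66e-05). The ubiquitin ligase genes skr-3, skr-4 and cul-6, part of the intracellular pathogen response, rose by 2.04, 1.98 and 1.36, and pals-38 rose by 1.32. The endoplasmic reticulum chaperone genes hsp-3, hsp-4 and enpl-1 rose by 0.99, 1.02 and 0.83, and the stress transcription factor xbp-1 by 0.97 (SE 0.12, adjusted p 0.00154). Of 26 neuron markers 11 were called higher (list adjusted p 1.92e-08, and 0.160 with an estimated correlation), among them the kinesin unc-104 by 0.73. The syntaxin unc-64 (0.93), the glutamate decarboxylase unc-25 (0.83) and the carboxypeptidase egl-21 (0.80) were called too, but each lost its call when 1 array was left out. The vitellogenin genes vit-1 and vit-4 fell by 2.63 and 1.48, while vit-2 differed by -0.05 (SE 0.12, adjusted p 0.847).

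The largest rises by the naming rule were those of warf-1, an ARF-related GTPase (7.52, SE 0.24, adjusted p 7.42e-07), Y41C4A.32 (5.66), Y37H2A.14 (5.58), the beta-tubulin tbb-6 (5.08), fat-7 (4.89), F22E5.6 (4.70), ZK593.3 (4.54), the methionine sulfoxide reductase msra-1 (4.45), B0205.13 (4.43) and the sirtuin sir-2.3 (4.41). The largest falls were those of pud-4 (-5.34, SE 0.66, adjusted p 0.00157), pud-3 (-4.66), the sphingomyelinase asm-3 (-4.11), sysm-1 (-3.60), C09B8.4 (-3.53), the saposin-like spp-4 (-3.43), T27A10.8 (-3.14), txt-4 (-3.05), E02H4.7 (-2.96) and F59D8.3 (-2.84). Another 4 features, each carrying several gene names, fell further, and their genes cannot be named. In sams-1 RNAi pud-3 and pud-4 averaged 2.26 and 3.13, under the dim-feature value of 3.43, so the sizes and ranks of their falls are uncertain, and the same holds for the rise of pals-38 from 2.91. In total 2232 features (7.61%) were called in limma, 1661 higher and 571 lower, and 1000 of them changed at least 2-fold. Every called gene named here by the rule had all 3 arrays of one group above all 3 of the other. For the largest rises and falls the rule itself required this. Groups did not overlap in 7752 features (26.4%), where chance gives 10%, and 7411 had an unadjusted p under 0.05. The count was 927 without sams-1 RNAi replicate 2, 1299 without empty vector replicate 1 and 2326 without the outlying empty vector replicate 3. It was 1140 in a fit of only these 2 groups and 3770 with array weights. Higher calls were 812 without sams-1 RNAi replicate 2, 990 without empty vector replicate 1 and 957 in the 2-group fit. Lower calls moved more: they were 115 without sams-1 RNAi replicate 2, 295 without its replicate 1, 309 without empty vector replicate 1, 337 and 318 without sbp-1 RNAi replicates 1 and 2, 183 in the 2-group fit and 1395 with array weights. Leaving out 1 array ended the calls of pcyt-1 (adjusted p 0.0754), hsp-4 (0.0671), unc-64 (0.0542) and egl-21 (0.0843) without sams-1 RNAi replicate 2, and of unc-25 (0.0580), vit-4 (0.113), T27A10.8 (0.0506) and F59D8.3 (0.0776) without empty vector replicate 1.

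The list tests for arrays labelled sams-1 RNAi called 18 of 39 lists and families, 13 upward and 5 downward, and 0 of them held with an estimated correlation. With fry the calls of germline (adjusted p 0.370) and intestine markers (0.0777), UDP-glucuronosyltransferases (0.307) and neuropeptide genes (0.0679) ended, and the others held. Fry also gave an adjusted p under 0.05 for methionine and folate genes (0.00758), fatty acid oxidation genes (0.0219) and dod genes (0.0472). Of 25 fatty acid synthesis genes 11 were called higher and 0 lower (13 and 0 adjusted over the list alone), with a list mean of 0.85 and adjusted p 1.5e-10, and adjusted p = 0.145 with an estimated correlation. Of 22 phospholipid genes 5 were higher and 0 lower (8 and 1 adjusted over the list alone; list adjusted p 4.94e-04, and 0.129 with an estimated correlation). Of 17 p38 components 11 were higher and 0 lower (11 and 1 adjusted over the list alone; list adjusted p 3.71e-09, and 0.129 with an estimated correlation). Of 26 intracellular pathogen response genes 9 were higher and 0 lower (10 and 0 adjusted over the list alone; list adjusted p 2.17e-04, and 0.129 with an estimated correlation). Of 20 endoplasmic reticulum stress genes 12 were higher and 0 lower (16 and 0 adjusted over the list alone; list adjusted p 6.22e-11, and 0.145 with an estimated correlation). Of 26 neuron markers 11 were higher and 0 lower (13 and 0 adjusted over the list alone; list adjusted p 1.92e-08, and 0.160 with an estimated correlation). Intestine markers (adjusted p 0.00642, and 0.424 with an estimated correlation), pharynx markers (0.00237, and 0.129) and DAF-16 induced genes (0.0269, and 0.424) were called upward. Germline markers (0.0375, and 0.778 with an estimated correlation) and vitellogenins (0.0251, and 0.440) were called downward. Without empty vector replicate 1 the germline (adjusted p 0.298), intestine (0.0553) and DAF-16 (0.0778) calls ended, without replicate 3 the vitellogenin call (0.0871), and a filter on dim features ended the DAF-16 call (0.238). Methionine and folate genes had 5 members higher and 1 lower (6 and 1 adjusted over the list alone), but the list was not called (adjusted p 0.0725). Its adjusted p was under 0.05 without sams-1 RNAi replicate 2 (0.0421) and with fry (0.00758). Pathogen effectors had 12 of 54 higher and 8 lower (13 and 13 adjusted over the list alone; list adjusted p 0.700), and fatty acid oxidation genes 7 of 30 higher and 2 lower (8 and 5 adjusted over the list alone; list adjusted p 0.233).

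In arrays labelled sbp-1 RNAi, 11 of 25 fatty acid synthesis genes were called lower than in empty vector and 1 higher (list adjusted p 3.65e-11, and 0.115 with an estimated correlation). The desaturase fat-7 fell by 2.35 (log2, SE 0.35, adjusted p 0.00576), from 7.57 ± 0.06 to 5.22 ± 0.85 (SD, n = 3), fat-6 by 1.03 (SE 0.18, adjusted p 0.0158) and the delta-12 desaturase fat-2 by 1.56 (SE 0.26, adjusted p 0.00913). The gene fat-5 differed by -1.35 (SE 0.33, adjusted p 0.0693). The elongase gene elo-2 fell by 2.28 (SE 0.23, adjusted p 5.69e-04) and elo-6 fell by 3.28 (SE 0.65, adjusted p 0.0271). The acyltransferase dgat-2 rose by 1.23 (SE 0.16, adjusted p 0.00296). The carboxylase pod-2 differed by -0.50 (adjusted p 0.0665) and fasn-1 by -0.17 (adjusted p 0.706). The methyltransferase pmt-2 fell by 1.94 (SE 0.42, adjusted p 0.0403). The other methyltransferase gene pmt-1 differed by -0.51 (adjusted p 0.335) and pcyt-1 by -0.46 (adjusted p 0.278). The hydroxyacyl-CoA dehydrogenase hacd-1 fell by 2.60 and the peroxisomal transporter pmp-5 fell by 2.67. Of 19 folate and methionine cycle genes 5 were called lower (list adjusted p 2.64e-04, and 0.0934 with an estimated correlation), among them gldc-1 (-1.94), atic-1 (-1.20), gcst-1 (-0.72) and ahcy-1 (-0.57). The last 2 lost their calls with a replicate block (0.0763 and 0.0909). The propionate genes hphd-1 and hach-1 fell by 2.72 and 1.17, and acdh-1 differed by -3.29 (SE 1.00, adjusted p 0.163).

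In the arrays labelled sbp-1 RNAi, 17 of 54 pathogen effectors were called higher and 1 lower, and 36 were not called (list adjusted p 6.06e-12, and 0.115 with an estimated correlation). The infection response gene irg-6 rose by 3.65 (SE 0.22, adjusted p 5.29e-05), from 4.24 ± 0.23 to 7.90 ± 0.37 (SD, n = 3), dod-22 by 3.34 (SE 0.25, adjusted p 1.07e-04), the lysozyme lys-3 by 3.18 (SE 0.18, adjusted p 3.78e-05), hpo-6 by 3.14 and irg-1 by 2.37 (SE 0.30, adjusted p 0.00211). From the p38 list cebp-1, vhp-1, pmk-3 and nipi-3 rose by 1.54, 1.43, 1.16 and 0.90. The intracellular pathogen response genes skr-5, skr-4, skr-3 and pals-39 rose by 2.92, 2.54, 2.06 and 1.17, the last from a dim 2.52. Of 20 endoplasmic reticulum stress genes 4 were called higher (list adjusted p 1.02e-10, and 0.121 with an estimated correlation), among them pdi-6 by 0.86, hsp-3 by 0.69 and crt-1 by 0.63. The chaperone hsp-4 differed by 0.79 (SE 0.21, adjusted p 0.0977). The genes cbs-1 (0.04, adjusted p 0.964) and vit-2 (-0.18, adjusted p 0.605) were not called.

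The largest rises were those of B0024.4 (6.82, SE 0.32, adjusted p 1.23e-05), C50F7.5 (6.47), Y37H2A.14 (5.89), the lectin clec-42 (5.23), warf-1 (5.08), Y41C4A.32 (4.91), the tetraspanin tsp-1 (4.89), W02A2.9 (4.72), dct-17 (4.48) and Y47H10A.5 (4.46). The largest falls were those of the aspartyl protease asp-13 (-3.995, SE 0.73, adjusted p 0.0175), elo-6 (-3.28), F22F7.8 (-3.21), the saposin-like spp-17 (-3.18), C09B8.4 (-3.14), F48D6.4 (-2.86), spp-23 (-2.75), the nuclear receptor nhr-114 (-2.72, SE 0.27, adjusted p 5.51e-04), hphd-1 (-2.72) and pmp-5 (-2.67). Calls numbered 815 (2.78% of features), 681 higher and 134 lower, of which 569 changed at least 2-fold. Groups did not overlap in 4731 features (16.14%, with 10% from chance), and 3793 had an unadjusted p under 0.05. Calls numbered 830 with the replicate number as a block, which added fat-5 (adjusted p 0.0366) and hsp-4 (0.0449) and dropped ahcy-1 (0.0909) and gcst-1 (0.0763). They numbered 462 without sbp-1 RNAi replicate 1, 517 without replicate 2, 826 without empty vector replicate 3 and 1686 with array weights. Higher calls were 408 without sbp-1 RNAi replicate 1 and 1221 with array weights. Lower calls were 54, 52 and 211 without sbp-1 RNAi replicates 1, 2 and 3, 88 without empty vector replicate 1, 86 without sams-1 RNAi replicate 3, 54 in the 2-group fit and 465 with array weights. Without sbp-1 RNAi replicate 1 the calls of fat-2 (adjusted p 0.0541), elo-6 (0.128), pmt-2 (0.166), hphd-1 (0.167), hach-1 (0.0973), gldc-1 (0.106), atic-1 (0.184), gcst-1 (0.194), ahcy-1 (0.198), asp-13 (0.0896), C09B8.4 (0.0632), nipi-3 (0.111), hsp-3 (0.119), pdi-6 (0.111) and crt-1 (0.149) ended. That of fat-6 ended without replicate 2 (0.0789), and without replicate 3 acdh-1 was called at -4.59 (0.00595) and fat-5 at -1.62 (0.0428).

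The list tests for arrays labelled sbp-1 RNAi called 16 lists and families, 8 upward and 8 downward, and 0 held with an estimated correlation. With fry the calls of propionate genes (adjusted p 0.0790), muscle markers (0.540), collagens (0.0855), nuclear hormone receptors (0.0881) and cytosolic ribosomal proteins (0.291) ended, and the others held. Fatty acid synthesis had 11 genes lower and 1 higher (16 and 1 adjusted over the list alone), with a list mean of -0.77 and adjusted p 3.65e-11, and adjusted p = 0.115 with an estimated correlation. Methionine and folate genes had 5 of 19 lower and 0 higher (7 and 0 adjusted over the list alone; list adjusted p 2.64e-04, and 0.0934 with an estimated correlation). Propionate genes had 2 of 12 lower and 0 higher (5 and 0 adjusted over the list alone; list adjusted p 5.56e-04, and 0.363 with an estimated correlation). Fatty acid oxidation genes had 4 lower and 1 higher (9 and 2 adjusted over the list alone; list adjusted p 0.0249, and 0.115 with an estimated correlation), a call that ended without empty vector replicate 2 (0.0581). Pathogen effectors had 17 higher and 1 lower (26 and 2 adjusted over the list alone), with a list mean of 0.78 and adjusted p 6.06e-12, and adjusted p = 0.115 with an estimated correlation. The p38 components had 6 higher and 0 lower (10 and 0 adjusted over the list alone; list adjusted p 1.96e-09, and 0.115 with an estimated correlation). Intracellular pathogen response genes had 7 higher and 0 lower (7 and 0 adjusted over the list alone; list adjusted p 6.53e-04, and 0.115 with an estimated correlation). Endoplasmic reticulum stress genes had 4 higher and 0 lower (12 and 0 adjusted over the list alone; list adjusted p 1.02e-10, and 0.121 with an estimated correlation). Phospholipid genes had 1 higher and 1 lower (list adjusted p 0.287), and neuron markers 1 higher and 0 lower (list adjusted p 0.639). Pharynx markers were called upward (adjusted p 0.0191, and 0.115 with an estimated correlation), a call that quantile normalization (0.0802), cyclic loess (0.0559), a dim filter (0.103) or leaving out sbp-1 RNAi replicate 3 (0.105) ended. Muscle markers, with 0 of 22 called, were called downward as a list (adjusted p 0.0306, and 0.870 with an estimated correlation), a call that ended without empty vector replicate 3 (0.913). Intestine markers (adjusted p 0.0831), germline markers (0.890) and vitellogenins (0.0793) were not called, but without that array intestine markers were called upward (0.00384) and germline markers downward (0.00351).

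**Figure D2:**
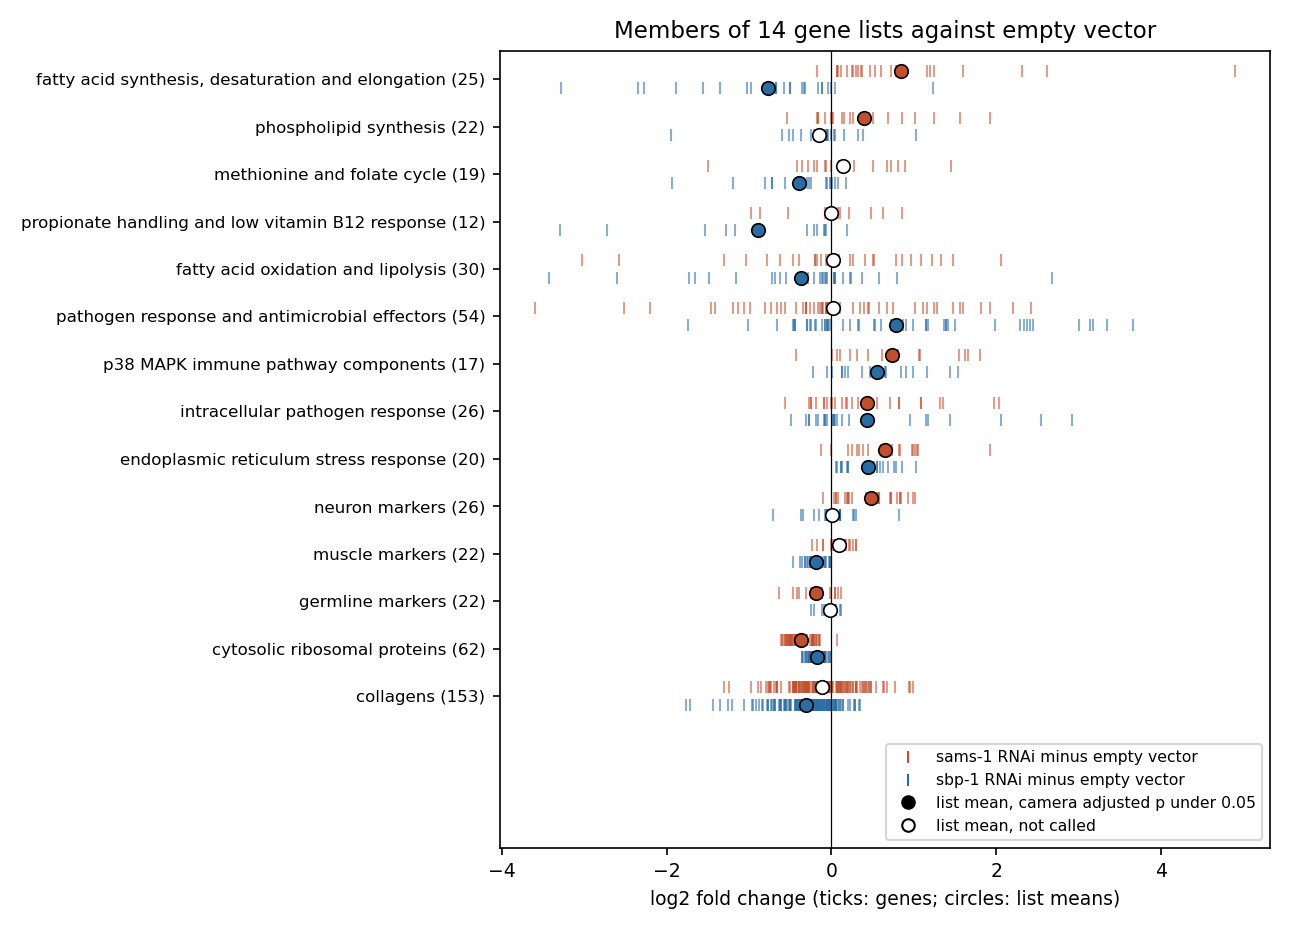
Log2 fold change against empty vector of the genes of 14 lists (ticks) and their means (circles, filled where camera gave an adjusted p under 0.05) for both RNAi groups, with the number of genes measured in parentheses. The fatty acid synthesis list averages 0.85 in arrays labelled sams-1 RNAi and -0.77 in arrays labelled sbp-1 RNAi, and lists named with p38 or endoplasmic reticulum stress average above 0 in both.

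Compared directly, 18 of 25 fatty acid synthesis genes and 6 of 22 phospholipid genes were called higher in arrays labelled sams-1 RNAi than in those labelled sbp-1 RNAi, and 0 lower. Among them were fat-7 by 7.24 (log2, SE 0.35, adjusted p 1.57e-05), fat-5 by 3.97 (SE 0.33, adjusted p 2.14e-04), elo-2 by 3.52, fat-6 by 2.62, pmt-2 by 2.63 (SE 0.42, adjusted p 0.00943), cept-1 by 2.16, pmt-1 by 1.75, pod-2 by 1.31, pcyt-1 by 1.31 and lpin-1 by 1.20. The gene fasn-1 differed by 0.36 (SE 0.15, adjusted p 0.384). The methionine and folate genes metr-1, mthf-1, mel-32 and mtrr-1 were higher by 1.79, 1.16, 1.14 and 0.81. The receptor nhr-114 was higher by 4.01 (SE 0.27, adjusted p 7.26e-05) and nhr-80 by 1.45. Of the 54 pathogen effectors 15 were called lower in arrays labelled sams-1 RNAi than in those labelled sbp-1 RNAi and 1 higher (list adjusted p 4.73e-11, and 0.127 with an estimated correlation). Genes called lower included irg-6 at -3.91 (SE 0.22, adjusted p 3.41e-05), irg-4 at -3.91, dod-22 at -3.90, lys-3 at -3.52 and, from the intracellular pathogen response, skr-5 at -2.21. The gene irg-1 differed by -0.44 (adjusted p 0.630), hsp-4 by 0.23 (0.743), cbs-1 by -0.40 (0.557), vit-2 by 0.13 (0.757) and acdh-1 by 3.50 (0.138). Other large differences were those of ZK593.3 (5.204), C30G12.2 (5.03), the lysozyme lys-4 (4.86), msra-1 (4.69), hacd-1 (4.66), T05E12.6 (4.41), sir-2.3 (4.21), the enoyl-CoA hydratase ech-7 (4.21) and pmp-5 (4.08) on the higher side. On the lower side were C50F7.5 (-5.05), Y68A4A.13 (-4.78), sysm-1 (-4.40), Y46D2A.2 (-4.30 and -3.82 in 2 features), T26H5.9 (-3.94) and pud-4 (-3.84). With group averages under the dim-feature value of 3.43 in sams-1 RNAi, the sizes for pud-4, dod-22 and lys-3 are uncertain.

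Between the RNAi groups 681 features were called (2.32%), 460 higher and 221 lower in arrays labelled sams-1 RNAi, and 478 differed at least 2-fold. Groups did not overlap in 5597 features (19.1%, with 10% from chance), and 3603 had an unadjusted p under 0.05. The count fell to 430 without sams-1 RNAi replicate 2, 429 without sbp-1 RNAi replicate 1 and 401 without sbp-1 RNAi replicate 2, and was 1251 with array weights. Higher calls were 259, 286 and 251 without those arrays in turn and 856 with array weights, and lower calls were 143 without sbp-1 RNAi replicate 1 and 395 with array weights. The call of pud-4 ended without sams-1 RNAi replicate 2 (adjusted p 0.0711), and acdh-1 was called without sbp-1 RNAi replicate 3 (4.81, adjusted p 0.00629). Of 22 lists and families called, 4 held with an estimated correlation, each at adjusted p 0.0279: fatty acid synthesis with 18 of 25 genes higher and 0 lower (20 and 0 adjusted over the list alone; preset adjusted p 1.56e-32), phospholipid synthesis with 6 and 0 (8 and 0 adjusted over the list alone; 3.88e-07), methionine and folate genes with 8 and 0 (11 and 1 adjusted over the list alone; 3.14e-07) and fatty acid oxidation with 7 and 2 (13 and 5 adjusted over the list alone; 7.04e-05). The fatty acid oxidation list also holds lipolysis genes and the nuclear receptor genes nhr-13, nhr-49, nhr-66 and nhr-80. Its call is therefore not one of oxidation enzymes alone. Pathogen effectors were called downward with 15 lower and 1 higher (21 and 2 adjusted over the list alone). Their list adjusted p was 4.73e-11, and 0.127 with an estimated correlation. Neuron markers were called upward with 1 higher and 0 lower (15 and 0 adjusted over the list alone; adjusted p 3.70e-11, and 0.129 with an estimated correlation), as were propionate genes with 2 and 0 (5 and 0 adjusted over the list alone; 1.80e-06, and 0.254). Small upward calls of p38 components (0.0156, and 0.431 with an estimated correlation) and endoplasmic reticulum stress genes (0.00122, and 0.431) came with 0 members called, the first ending without sbp-1 RNAi replicate 3 (0.0943), and intracellular pathogen response genes were not called (0.790). Muscle markers (8.31e-05, and 0.487 with an estimated correlation), sperm markers (0.00292, and 0.431) and DAF-16 induced genes (0.0113, and 0.381) were called upward. Germline markers were called downward (0.00720, and 0.572), a call that ended without sams-1 RNAi replicate 3 (0.0767). With fry the calls of p38 components (adjusted p 0.161), endoplasmic reticulum stress genes (0.142), muscle (0.228), sperm (0.169) and germline markers (0.373) ended. So did those of UDP-glucuronosyltransferases (0.0893), collagens (0.344), cytosolic ribosomal proteins (0.169), neuropeptide genes (0.0691), vacuolar ATPase subunits (0.11) and major sperm proteins (0.21), and the others held.

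Lists on other themes were not called in any comparison. Adjusted p against empty vector was 0.632 and 0.424 for oocyte markers, 0.688 and 0.140 for larval cuticle and molting markers, and 0.665 and 0.668 for hypodermis markers, in arrays labelled sams-1 RNAi and sbp-1 RNAi in turn. It was 0.700 and 0.218 for histone methylation genes, 0.688 and 0.639 for mitochondrial stress genes, 0.659 and 0.530 for heat shock genes, and 0.287 and 0.997 for oxidative stress genes. Leaving out 1 array brought calls of oocyte markers in sams-1 RNAi (downward, 0.0124 without empty vector replicate 3), and in sbp-1 RNAi of histone methylation genes (upward, 0.0252 without empty vector replicate 1) and molting markers (upward, 0.0247 without sbp-1 RNAi replicate 3). List mean, list median and test differed in sign in 8 lists for sams-1 RNAi, among them propionate genes, pathogen effectors and fatty acid oxidation, in 5 for sbp-1 RNAi and in 3 between the RNAi groups, and 0 of these were called. Some genes serve several lists: ckb-2 is in the phospholipid and endoplasmic reticulum lists, elt-2 in the p38 and intestine lists, and 20 of the 54 pathogen effectors are in another list or family.

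Genes higher in both RNAi groups included warf-1, Y41C4A.32, Y37H2A.14, hpo-6, skr-3, skr-4, vhp-1, cebp-1 and dgat-2. In total 482 features were higher in both, 70.8% of those higher in sbp-1 RNAi, where independent calls would give 38.6, and 44 were lower in both, spp-1 and C09B8.4 among them, against 2.61. Both groups share the empty vector arrays. Unchanged groups, simulated with a common simulated empty vector group, shared on average 96.2 higher and 96.2 lower features. Their medians were 0 and their highest values 4474 and 3895. In each direction 4% of these 100 simulations shared as many as observed, and the 44 lower features lie under the simulated mean. With independent noise the averages were 0.4 and 0.49 and the highest values 3 and 5. The fold changes of both groups had a covariance of 0.128 across features, against 0.0362 simulated on average and 0.179 at most, and genes are not independent replicates. Their correlation was 0.626, against 0.548 simulated on average and 0.970 at most, and 0.640 on average with independent noise. The correlation thus does not set these groups apart from unchanged ones. Shared higher calls fell to 292 without empty vector replicate 1, 300 without sbp-1 RNAi replicate 1 and 317 without sbp-1 RNAi replicate 2, and shared lower calls to 14 without sbp-1 RNAi replicate 1, 17 without replicate 2, 25 without sams-1 RNAi replicate 1, and 20 without its replicate 2 or 3. Array weights gave 900 and 202. In the direct comparison, 454 of the 2232 features called for sams-1 RNAi (20.3%) and 221 of the 815 called for sbp-1 RNAi (27.1%) also differed between the RNAi groups.

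Opposite calls came to 23 features higher in sams-1 RNAi and lower in sbp-1 RNAi and 5 the other way. Independent calls would give 7.59 and 13.3. Unchanged groups, simulated with a common simulated empty vector group, gave 0.29 and 0.32 on average. The highest simulated values were 29 and 21, and 1% and 2% of these 100 simulations gave as many as observed. Simulations with independent noise gave at most 0 of either kind. The 28 became 11 without empty vector replicate 1, 16 without its replicate 2, 15 without sbp-1 RNAi replicate 1, 13 without its replicate 2, 14 without sams-1 RNAi replicate 2 and 17 without its replicate 3. They became 12 in fits of only the groups compared and 64 with array weights. Named after their values were seen, the first kind held 6 of the 25 fatty acid synthesis genes, among them fat-7, fat-6, fat-2 and elo-2, and also hacd-1, ech-7, pmp-5 and nhr-114. The 5 others, likewise chosen after their values were seen, were Y68A4A.13 (-1.77 in sams-1 RNAi and 3.01 in sbp-1 RNAi), Y46D2A.2 (-1.11 and 3.19), drd-50 (-1.58 and 1.95), F49F1.7 (-1.44 and 1.65) and gst-20 (-0.96 and 0.89). Any difference among the 3 groups was called in 1909 features (6.51%) by limma's F test, in 1217 without empty vector replicate 1, 1228 without sams-1 RNAi replicate 2 and 3347 with array weights.

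**Figure D3:**
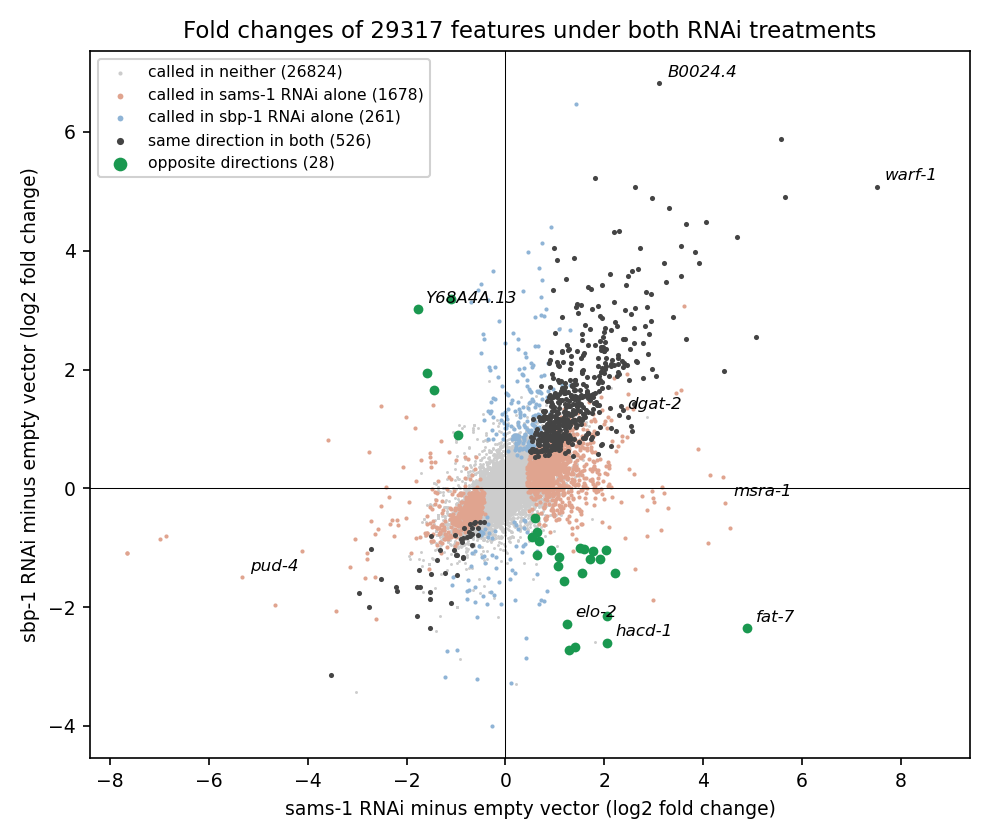
Log2 fold change of 29317 features against empty vector in arrays labelled sams-1 RNAi (horizontal axis) and sbp-1 RNAi (vertical axis), with 1 point per feature coloured by where it was called. The 482 features higher in both lie at the upper right, and fat-7 lies at 4.89 and -2.35 among the 23 features higher in one and lower in the other.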

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

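The alternatives were planned before the data were examined, except the fit of only the features with 1 gene name, which was chosen after seeing the data. No count of calls moved more than 1.5 times under a replicate block, quantile normalization, median centring, cyclic loess, the dim filter, trended robust eBayes or the single-name fit, and no called feature changed sign. In the fit of only the 2 groups compared, sams-1 RNAi calls numbered 1140 and shared lower calls 18, with fewer arrays behind each spread. Array weights gave 3770 calls for sams-1 RNAi, 1686 for sbp-1 RNAi, 1251 between the RNAi groups, 3347 for any difference, 900 shared higher and 202 shared lower; they gave the outlying empty vector array a weight of 0.236. A 2-fold minimum left 1000 calls for sams-1 RNAi, 292 shared higher and 20 shared lower, as a stricter threshold must leave fewer.

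Leaving out each array in turn gave 927 (without sams-1 RNAi replicate 2) to 2326 calls (without empty vector replicate 3) for sams-1 RNAi, 462 (without sbp-1 RNAi replicate 1) to 852 (without its replicate 3) for sbp-1 RNAi, and 401 (without sbp-1 RNAi replicate 2) to 823 (without empty vector replicate 3) between the RNAi groups. It gave 1217 to 2004 for any difference, 292 to 531 for shared higher and 14 to 56 for shared lower calls. Where the cause is not given here, the cause was not tested.

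Of 380 values of named genes, 74 lost their call and 23 gained one in at least 1 fit without an array, 54 lost it in the fit of only the 2 groups, 19 lost it and 7 gained it with a replicate block, 13 lost it with quantile normalization, 12 with median centring and 15 with cyclic loess, and 25 gained it with array weights. Of 117 list results, 52 of the 56 called lost their call with an estimated correlation, 20 with fry and 14 when 1 array was left out. Among those not called, 3 gained a call with fry and 16 when 1 array was left out. Dim features limit what the arrays can show: 364 of the 380 values passed the filter at a log2 intensity of 3.43.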

Other observations

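The tests of explanations below were all chosen after the results they bear on were seen; the regroupings of the arrays, except the 36 that spread replicate numbers over the groups, and the gene families were planned.

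Gene families outside the report's comparisons moved as follows, with calls adjusted over all features. Nuclear hormone receptor genes had 51 of 272 members higher and 1 lower in arrays labelled sams-1 RNAi (67 and 2 adjusted over the list alone), nhr-3 by 1.85 and nhr-35 by 1.25 among them, with a family adjusted p of 1.05e-06, and 0.129 with an estimated correlation. In sbp-1 RNAi 9 were higher and 2 lower (0.00158, and 0.227 with an estimated correlation), and between the RNAi groups 15 and 2 (5.11e-04, and 0.254). F-box A genes had 34 of 188 higher in sams-1 RNAi and 19 in sbp-1 RNAi (37 and 28 adjusted over the list alone), with fbxa-150 up by 1.96 and 2.03 and adjusted p 2.86e-04 and 8.07e-06 (0.145 and 0.115 with an estimated correlation). Between the RNAi groups F-box A genes were not called (0.731). Neuropeptide genes had 21 of 148 higher and 1 lower in sams-1 RNAi (42 and 2 adjusted over the list alone), flp-34 by 1.79 among them, with adjusted p 5.36e-10, and 0.424 with an estimated correlation; 9 of the 148 are in another list, and they moved together with the neuron markers. They were not called in sbp-1 RNAi (0.793) but were between the RNAi groups (2.24e-16, and 0.318 with an estimated correlation). Relative to the mean of all 9 arrays, neuropeptide genes averaged 0.0146, 0.451 and 0.247 in sams-1 RNAi replicates 1 to 3. In empty vector they averaged -0.205, -0.135 and 0.0237, so sams-1 RNAi replicate 1 lay under empty vector replicate 3.

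Cytosolic ribosomal protein genes averaged -0.37 in sams-1 RNAi, with 5 of 62 called lower (37 adjusted over the list alone), rps-24 by -0.60 among them until sams-1 RNAi replicate 2 was left out (adjusted p 0.0756). The family adjusted p was 3.48e-12, and 0.424 with an estimated correlation. In sbp-1 RNAi the family averaged -0.18 with 0 members called (1.96e-05, and 0.761), and it differed between the RNAi groups (1.09e-07, and 0.494). Proteasome subunits averaged -0.26 in sams-1 RNAi (1.42e-05, and 0.424 with an estimated correlation), were not called in sbp-1 RNAi (0.668) and were called lower in sams-1 RNAi than in sbp-1 RNAi (3.00e-07, and 0.381). UDP-glucuronosyltransferase genes had 10 of 67 higher and 3 lower in sams-1 RNAi (0.0269, and 0.759 with an estimated correlation), ugt-66 by 1.96 and ugt-53 by -2.77 (to a dim 3.42, so its size is uncertain), a call that ended with quantile normalization (0.0597), cyclic loess (0.0707) and without empty vector replicate 2 (0.285). In sbp-1 RNAi they were not called (0.1), and they differed between the RNAi groups (3.36e-06, and 0.431). Collagen genes averaged -0.31 in sbp-1 RNAi with 0 of 153 members called (7.90e-07, and 0.263 with an estimated correlation) and -0.12 in sams-1 RNAi (0.125), and the difference of 0.19 between the RNAi groups was called (0.00720, and 0.494) until sams-1 RNAi replicate 1 was left out (0.334). The family of dod genes averaged 1.36 in sbp-1 RNAi with 4 of 9 higher (6 adjusted over the list alone), dod-20 by 2.80 and dod-24 by 2.29 among them (1.96e-09, and 0.0934 with an estimated correlation); 6 of the 9 are in another list, and the family was not called in sams-1 RNAi, where it averaged 0.40 with 3 higher and 1 lower (5 and 2 adjusted over the list alone; 0.0847, and 0.440 with an estimated correlation). It differed by -0.96 between the RNAi groups, sams-1 RNAi minus sbp-1 RNAi (2.38e-04, and 0.178). Chemoreceptor genes averaged -0.13 in sams-1 RNAi (0.00174, and 0.208 with an estimated correlation) and -0.10 in sbp-1 RNAi (0.00319, and 0.226), and quantile normalization ended both calls (0.534 and 0.673). Against empty vector, C-type lectins (0.322 and 0.890), cytochrome P450 genes (0.765 and 0.961), glutathione S-transferases (0.659 and 0.643), vacuolar ATPase subunits (0.285 and 0.218), major sperm proteins (0.233 and 0.643) and histones (0.730 and 0.413) were not called (sams-1 RNAi first, then sbp-1 RNAi). Between the RNAi groups, vacuolar ATPase subunits averaged 0.15 (0.00373, and 0.431 with an estimated correlation) and major sperm proteins 0.66 (0.0201, and 0.431), both higher in sams-1 RNAi with 0 members called. These calls ended without sbp-1 RNAi replicate 2 (0.0816) and without sams-1 RNAi replicate 1 (0.153).

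Arrays labelled sbp-1 RNAi differed among themselves in the propionate gene acdh-1, which read 8.504, 5.80 and 11.06 in replicates 1 to 3 against 11.68, 11.46 and 12.10 in empty vector. The elongase elo-6 read 7.31, 6.36 and 9.56 and the methyltransferase pmt-2 8.87, 8.06 and 10.12 in the same arrays, so that replicate 3 stood nearest to empty vector in all 3 genes.

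Neither targeted gene was called lower in the arrays labelled for it. If the labels of both RNAi groups had been exchanged, the arrays labelled sams-1 RNAi would be those with SREBP lowered, and lipid synthesis genes should be low in them. The fatty acid synthesis list averaged 0.845 there, which argues against an exchange. The gene sams-1 read -1.097 in the arrays labelled sbp-1 RNAi, as an exchange would have it, but was not called. An exchange would also have sbp-1 low in the arrays labelled sams-1 RNAi, where it read higher than in empty vector, likewise uncalled. Double-stranded RNA of the targeted gene, carried over in RNAi food, may have been read by the array, and with 1 feature per targeted gene this cannot be told apart from the gene's own transcript. Weak lowering of the targeted transcript was not tested and stays open.

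Empty vector array 3 stood apart from empty vector arrays 1 and 2. An RNAi array with an empty vector label would lie along an RNAi group's change with a slope near 1, whereas its slopes were 0.136 along sbp-1 RNAi and 0.135 along sams-1 RNAi, over features called without it. Its germline, oocyte and sperm markers averaged -0.44, -0.33 and -0.40 relative to the other arrays of its group, so fewer germ cells could be part of the difference. As the whole cause, acting only through the germ cells' share of the RNA, they would raise the markers of all other tissues alike. Muscle markers, however, averaged 0.46 and pharynx markers -0.12. That gap was 0.579 (SE 0.0996 over genes). Genes of a list can correlate, estimated at 0.62 for muscle and -0.0122 for pharynx markers, and array 3 has no replicate. The SE therefore leaves out the spread between arrays, and the gap does not decide whether fewer germ cells are the whole cause. A difference in the age or health of these animals was not tested and stays open.

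Features higher in both RNAi groups may owe part of their number to the shared empty vector arrays. With different empty vector arrays for each RNAi group, the covariance of fold changes across features was 0.0711 to 0.106 over 6 choices, all above 0. These choices reuse the same arrays, and no range for unchanged groups was simulated for them. They therefore do not decide whether chance values of the shared arrays are the whole cause. Fewer germ cells, if they acted only by lowering the germ cells' share of the RNA, would raise the genes of other tissues alike. Features chosen in some arrays would then rise in the remaining arrays no further than the markers of other tissues. Germline markers averaged -0.187 in sams-1 RNAi and -0.0234 in sbp-1 RNAi, and -0.334 and -0.171 without empty vector array 3. Features higher in both groups were chosen without 1 RNAi and 1 empty vector array and measured between those arrays. Over 9 choices per group they averaged 1.003 to 2.29 in sams-1 RNAi and 1.23 to 2.63 in sbp-1 RNAi. These averages argue against a lower share of germ cell RNA as the whole cause of the rise. Part of the features can carry these averages, however, and fewer germ cells may account for the others. A response of other tissues to fewer germ cells was not tested and stays open. The averages lay at least 3.38 SE above each tissue mean (bound 2.73). The SE is over genes, which correlate, and leaves out the spread between arrays, so the bound is no test over arrays. A looser choice tried first, features called higher in the other RNAi group alone, passed that bound in 5 of 6 cases and gave 2.23 SE in sbp-1 RNAi against empty vector array 3. Slower development cannot be told apart from the RNAi groups: larval cuticle and molting markers averaged 0.0357 in sams-1 RNAi and 0.102 in sbp-1 RNAi, too little to decide either way, and a response common to both treatments stays open.

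Other splits of the arrays were counted for each comparison. For any difference among the 3 groups, 1 of 100 splits, the real one, gave as many calls: 1909 against 325 in the highest of the others, so chance can be excluded. Of the 36 splits with 1 array of each replicate number in every group, counted after the others were seen, only the real one gave as many: the highest other gave 375, or 211 against 1994 with a replicate block (share 0.0278 each). For 3 arrays against 3 there are 10 splits, too few for a share under 0.05: the real split gave 2232 calls and the highest other 0 for sams-1 RNAi against empty vector, 815 and 1 for sbp-1 RNAi against empty vector, and 681 and 0 between the RNAi groups. For sbp-1 RNAi and empty vector, arrays of the same replicate number correlated more than others, which 3 arrays per group can also give by chance. The 4 splits that part all 3 pairs of equal number included the real one, and the others among them gave at most 0 calls.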
